A study of Mus musculus with 4 samples.

How the data were processed

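RNA was measured in 4 cultures of immortalized mouse embryonic fibroblasts, a fibroblast line made from mouse embryos, carrying an empty vector, Myc, MycN or a protein the labels call Minimal Myc. The cells received an adenovirus carrying Cre recombinase, an enzyme that cuts out DNA between its recognition sites; the series design describes the vector cells as having Myc deleted. Harvest followed a recovery given as 48, with no unit. Total RNA was enriched for polyadenylated RNA and made into libraries that keep strand by destroying the dUTP-marked strand. The labels also state that ERCC spike-in RNAs, synthetic transcripts of known amount, were added by cell number. The tables used here hold 0 rows of those spike-ins.

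Per the submitters' processing notes, TopHat2 2.0.11, Cufflinks 2.2.0 and the mouse build mm9 were used, with no role or order given. The authors deposited 2 tables of FPKM, fragments scaled to transcript length and to the total of the library, with 26608 identifier rows in each. Of these, 26576 rows carry FPKM. The other 32 rows, for 30 genes, carry a NanoString signal deposited in the same columns, a hybridization count of RNA molecules on another scale, whose normalization is not given in the sources used here. In the second table every value of a library equals that of the first multiplied by 1 factor per library. The factors are 1 for vector, 2.04 for Myc, 1.30 for MycN and 1.28 for Minimal Myc. Each equals the mean over the 32 NanoString rows of the ratio to vector, and the NanoString rows were multiplied as well. Gene names are the symbols in the files. No coordinates are given, because the reference used here is a later mouse build; it served only for transcript length and GC content, found for 11544 of 11640 genes (99.2%).

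Rows of a gene with identical values were merged and rows that differed were summed (187 of 23366 genes). Genes with a mean of at least 1 FPKM over the 4 libraries were kept, without 310 small RNA genes whose symbols start with Mir, Snora, Snord, Scarna or Rnu, which left 11640. A difference is that of log2(FPKM + 1) in the unscaled table, a scale that understates differences of low genes. With 1 library per group no test was run, no paired fit was possible and no p-value is given; genes were counted when they differed by at least 2-fold either way. FPKM carry no read depth, so the depth of each library is unknown and no counting interval is given.

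Before the data were examined, 29 gene lists were fixed: ribosome biogenesis, Myc targets (a hallmark-type list), nucleotide synthesis, polyamine synthesis, glycolysis, ribosomal proteins, translation factors, tRNA synthetases, serine and amino acid stress genes, endoplasmic reticulum chaperones, DNA replication, mitosis, p53 targets with cell cycle inhibitors, extracellular matrix, smooth muscle contractile genes, cholesterol synthesis, oxidative phosphorylation, lysosome, interferon response, inflammatory cytokines, immediate early genes, the Myc network, housekeeping genes, and markers of epithelial, immune, endothelial, adipocyte, skeletal muscle and neural cells. The lists overlap in part. The value of a list is the median difference of its measured members minus the median over 10000 random lists of the same size matched on mean expression in 20 bins. It is therefore relative to genes of like abundance. Its percentile among those random lists describes these libraries only. Members past the filter are called measured, and lists with at least 5 of them were given this description (24 lists).

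Named genes followed a rule also set before the data were examined. It takes the Myc network genes, the 8 highest and 8 lowest genes in each comparison with vector, the 5 highest and 5 lowest between Myc proteins, and up to 3 members of each described list with the largest difference. Symbols starting with Gm and a number, starting with LOC or ending in Rik were replaced by the next gene. The rule leaves out symbols listed more than once, which was read as genes whose rows differ after identical ones are merged. Genes named outside the rule (Malat1, Mir5109, Gm20594, and Rmrp as a sign of RNA type, Isg15, Ptma, and the genes of the closing section) were chosen after their values were seen. In the comparison of Minimal Myc with Myc, 1 gene that the rule takes is not reported here. Cufflinks can list a gene at 0 where its estimate failed; Acin1, a splicing factor gene of all cells, is listed at 0 in MycN alone. Such genes are marked in the text as listed at 0. Their place among the highest or lowest genes rests on that 0 and is not read as a large change. Ribosomal protein genes have near-identical processed copies, so their single values are uncertain.

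Comparisons with the same vector library share its chance values, so correlations stand beside those of 100 simulations in which nothing differs from vector, with noise taken from the Myc and MycN difference. The calculation was tested on simulated data for Myc against vector over 11640 genes. It recovered 100 of 100 genes made 8-fold higher and 95 of 100 made 8-fold lower. Of 11400 genes left alone, 582 (5.11%) passed 2-fold with noise of the assumed size. This noise also came from the Myc and MycN difference, which includes real differences, and no shift of all genes was simulated. The 5.11% is thus no rate of false calls in these libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Alternatives were a pseudocount of 0.1, a minimum of 5 FPKM or none, sizes of 1.5-fold and 3-fold, small RNA genes kept, the scaled table, and libraries centred on the median difference.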

Results

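RNA-seq measured gene expression in 4 cultures of immortalized mouse embryonic fibroblasts after Cre treatment, with 1 library each for empty vector, Myc, MycN and Minimal Myc. The question, per the series design, was how overall cellular expression differs between cells in which Myc was deleted and cells given one of these Myc proteins, transcription factors that drive growth genes. Read depth is unknown because the values are FPKM. No difference below has a replicate check.

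The targeted gene was examined before all others. Myc stood at 22.2 FPKM in vector, 141 in Myc, 4.36 in MycN and 32.6 in Minimal Myc. Mycn stood at 0.390 FPKM in vector, 0.275 in Myc, 178 in MycN and 95.9 in Minimal Myc. The labels do not say from which gene Minimal Myc was made. In cells given a Myc protein, FPKM of a whole gene cannot separate an added coding sequence from the cell's own transcript. An empty vector adds no such sequence, so the 22.2 FPKM in vector is assigned to the cells' own Myc gene. It was higher than in MycN. Whether it comes from parts of the gene left in place or from incomplete deletion was not tested. The vector cells are therefore not shown here to lack Myc. Max, the obligate partner of Myc, was 18.8 FPKM in vector and 34.5 to 37.3 in the others. Of the Max partners that compete with Myc, Mxd3 was 14.4 FPKM in vector, 36.9 in Myc, 23.6 in MycN and 29.6 in Minimal Myc, and Mnt was 5.52, 9.99, 8.17 and 10.05. Mxd4 was 12.8 FPKM in vector, 32.4 in Myc, 45.2 in MycN and 18.1 in Minimal Myc, and Mxi1 was 5.20, 12.1, 15.0 and 7.97 FPKM in the same order. Relative to matched genes the Myc network list of 12 measured genes stood at 0.22, 0.28 and 0.14 (log2) in Myc, MycN and Minimal Myc against vector. The list includes Myc and Mycn themselves, so it is not a measure of other network genes alone.

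By FPKM, which are relative to the library total, most genes were higher than in vector in all 3 libraries. Over 11640 genes the median log2 difference in unscaled FPKM was 0.47 for Myc, 0.42 for MycN and 0.47 for Minimal Myc. In the authors' scaled table it was 1.42, 0.76 and 0.80. NanoString, read on 30 genes, gave median ratios to vector of 2.04 for Myc (30 of 30 genes above vector), 1.28 for MycN (21 of 30) and 1.23 for Minimal Myc (25 of 30). Over the same genes the unscaled FPKM ratios had medians of 1.92, 1.71 and 1.65, and the scaled ones 3.92, 2.22 and 2.11. The unscaled FPKM ratio was above the NanoString ratio in 15 of 30 genes in Myc, 29 in MycN and 28 in Minimal Myc. In MycN and Minimal Myc, NanoString thus gave a smaller rise than FPKM for most of these genes. Npm1, a nucleolar chaperone of ribosome assembly, had a NanoString signal of 37173 in vector and 111489 in Myc, against 345 and 1054 FPKM. Ptma, the gene of an acidic nuclear protein, had a NanoString ratio of 3.08 in Myc and 2.55 in MycN. Across the 30 genes, which are not independent replicates, log2 ratios by NanoString and FPKM had Pearson's r of 0.829, 0.895 and 0.865.

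**Figure D1:**
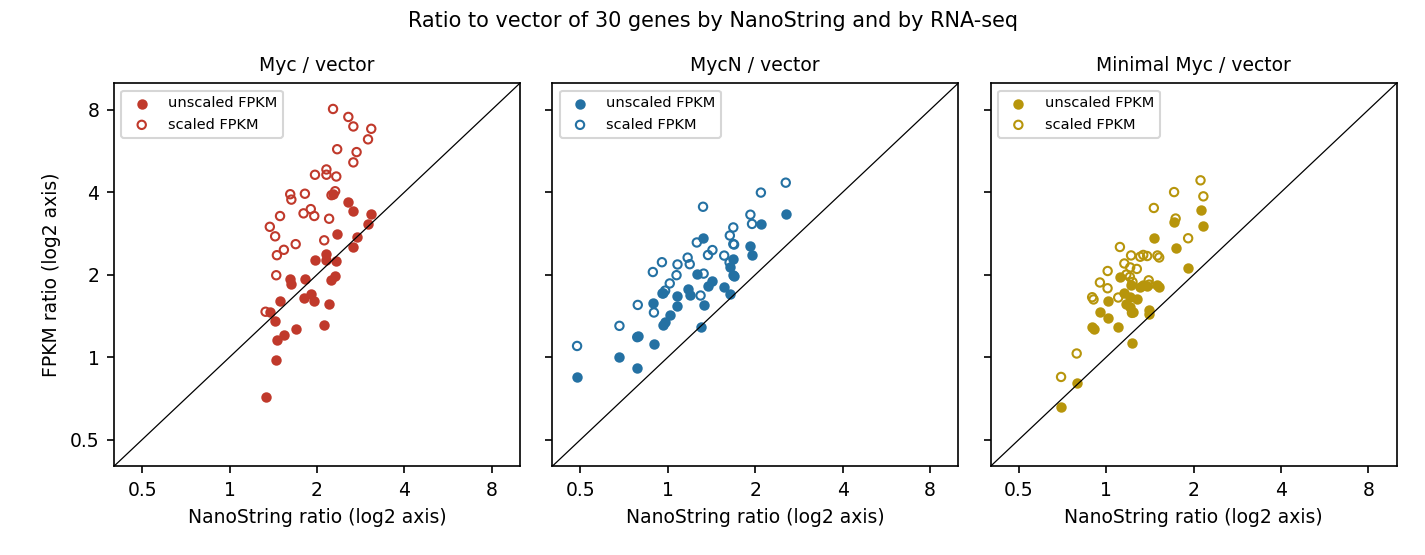
Ratio to vector of 30 genes by NanoString (x axis) and by RNA-seq (y axis), both on log2 axes without units, for Myc, MycN and Minimal Myc. Filled points are unscaled FPKM, open points scaled FPKM, and all 30 open points lie above the line of equal ratios in each panel.

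The libraries also differed in kinds of RNA other than messenger RNA. Coding genes held an estimated 52.0% of fragments in vector, 79.4% in Myc, 70.7% in MycN and 80.8% in Minimal Myc, from FPKM times transcript length. A higher median gene raises this share nearly by construction, so it is no separate support for a difference in kinds of RNA. Malat1, a nuclear non-coding RNA, was 381 FPKM in vector, 124 in Myc, 192 in MycN and 64.0 in Minimal Myc. Rmrp, an RNA without a poly(A) tail that forms part of a ribonuclease, was 118, 22.5, 57.7 and 14.9 FPKM. Mir5109, a small RNA gene left out by the filter, was 185861 FPKM in vector, where all rows summed to 605552. FPKM are scaled to length, so these values do not give the share of fragments of a small RNA. The level of Mir5109 was far lower in the other libraries. It was 6331 FPKM in Myc, 26320 in MycN and 7680 in Minimal Myc. Gm20594 was 4246 FPKM in vector, 160 in Myc, 635 in MycN and 106 in Minimal Myc. Rn45s, the ribosomal RNA precursor, is listed at 0 in vector and MycN and was 995 FPKM in Myc and 1059 in Minimal Myc. It is not read either way, because an estimate can fail. The shift of 0.42 to 0.47 sits under every count against vector, so gene groups are described relative to genes of matched expression.

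Against vector, the Myc library was higher in the machinery that makes ribosomes. Of 44 ribosome biogenesis genes, 36 were at least 2-fold higher and 0 lower, with a list value of 0.74 (log2) relative to matched genes. Nop16, a nucleolar assembly factor, was 66.3 FPKM against 13.8, and Ncl, the nucleolar protein nucleolin, was 221 against 59.9. Of 78 ribosomal protein genes, 52 were at least 2-fold higher (list value 0.41), and of 56 Myc target genes, 38 were (0.55), among them Pa2g4, a growth regulator, at 248 FPKM against 51.9. All 3 lists lay above every one of the 10000 random lists. The 2-fold counts include the shift of all genes. Relative to the median difference of all genes, 14 of 44 ribosome biogenesis genes were at least 2-fold higher. The same held for 5 of 78 ribosomal protein genes and 13 of 56 Myc target genes.

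Genes of nucleotide and polyamine synthesis and translation factors were also high in Myc. Of 30 nucleotide synthesis genes, 15 were at least 2-fold higher (list value 0.41), including Cad, which starts pyrimidine synthesis, at 55.2 FPKM against 16.6. Of 12 polyamine genes, 6 were (0.42), with the spermidine synthase gene Srm at 254 FPKM against 56.9. Of 39 translation factors, 17 were (0.22). Relative to the median difference of all genes, 6 of 30 nucleotide, 2 of 12 polyamine and 1 of 39 translation genes were at least 2-fold higher. The 95% bootstrap interval over members of the polyamine list spanned 0 (-0.35 to 0.75). Lists within the range of random lists were glycolysis (0.16), tRNA synthetases (-0.05), endoplasmic reticulum chaperones (0.11), DNA replication (0.11), mitosis (0.13), p53 targets (0.02), cholesterol synthesis (0.01), oxidative phosphorylation (-0.04) and housekeeping genes (0.08).

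Other groups were lower in Myc than matched genes. Lysosome genes, of degradation enzymes and their membrane proteins, stood at -0.55 over 31 genes, immediate early genes at -0.80 over 23, and smooth muscle contractile genes at -0.60 over 14. Klf4, an immediate early transcription factor, was 5.43 FPKM against 18.3, and Actg2, a smooth muscle actin, was 7.18 against 16.9. Extracellular matrix stood at -0.33 over 41 genes while its members went apart: Timp3, a metalloproteinase inhibitor, was 79.1 FPKM against 5.56, and Ctgf, a matricellular growth factor, was 16.8 against 119. Serine and amino acid stress genes (-0.42 over 24), interferon response (-0.24 over 37) and inflammatory cytokines (-0.37 over 16) were also low. In these 3 lists 2, 1 and 2 genes were at least 2-fold higher and 0, 3 and 0 lower. Extracellular matrix had 7 higher and 1 lower. Lysosome had 1 and 1, immediate early 0 and 2, and contractile genes 1 and 2. The 95% bootstrap interval over members spanned 0 for extracellular matrix (-0.61 to 0.09) and cytokines (-0.81 to 0.21). Before matching only the immediate early and smooth muscle medians of the 24 lists lay below 0 (-0.29 and -0.04). In scaled FPKM they were 0.62 and 0.92, and none of the 24 medians lay below 0. The lists above are thus low relative to other genes. Scaled ratios of Myc to vector were above the NanoString ratios in all 30 genes read by both. The scaled table therefore does not settle whether any of these lists lay below vector in level.

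The highest genes in Myc were Rn45s, the ribosomal RNA precursor, at 995 FPKM, and Lars2, Filip1l and Cdk8 at 273, 36.5 and 29.9, with Cmss1, all listed at 0 in vector. Their rank rests on that 0, which can be a failed estimate. The others among the 8 highest were Slpi, a secreted protease inhibitor, at 49.0 FPKM against 0.815, Gas6, a ligand of TAM receptors, at 22.7 against 0.298, and Grb10, an imprinted growth factor receptor adaptor, at 17.5 against 0.0977. The lowest were Lce1g (0.345 FPKM against 12.2), Pisd-ps1 (0.0192 against 6.56), Spon2 (1.06 against 13.8), the cornified envelope genes Sprr2h (0.538 against 9.41) and Sprr1a (2.84 against 23.6), Ctgf, Mcam (3.17 against 25.7) and Oasl1 (2.88 against 23.1). In all, 1300 genes were at least 2-fold higher and 182 lower. Centred on the median difference the counts were 218 and 510, and with scaled FPKM 9139 and 58, so the split between higher and lower depends on the scaling.

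**Figure D2:**
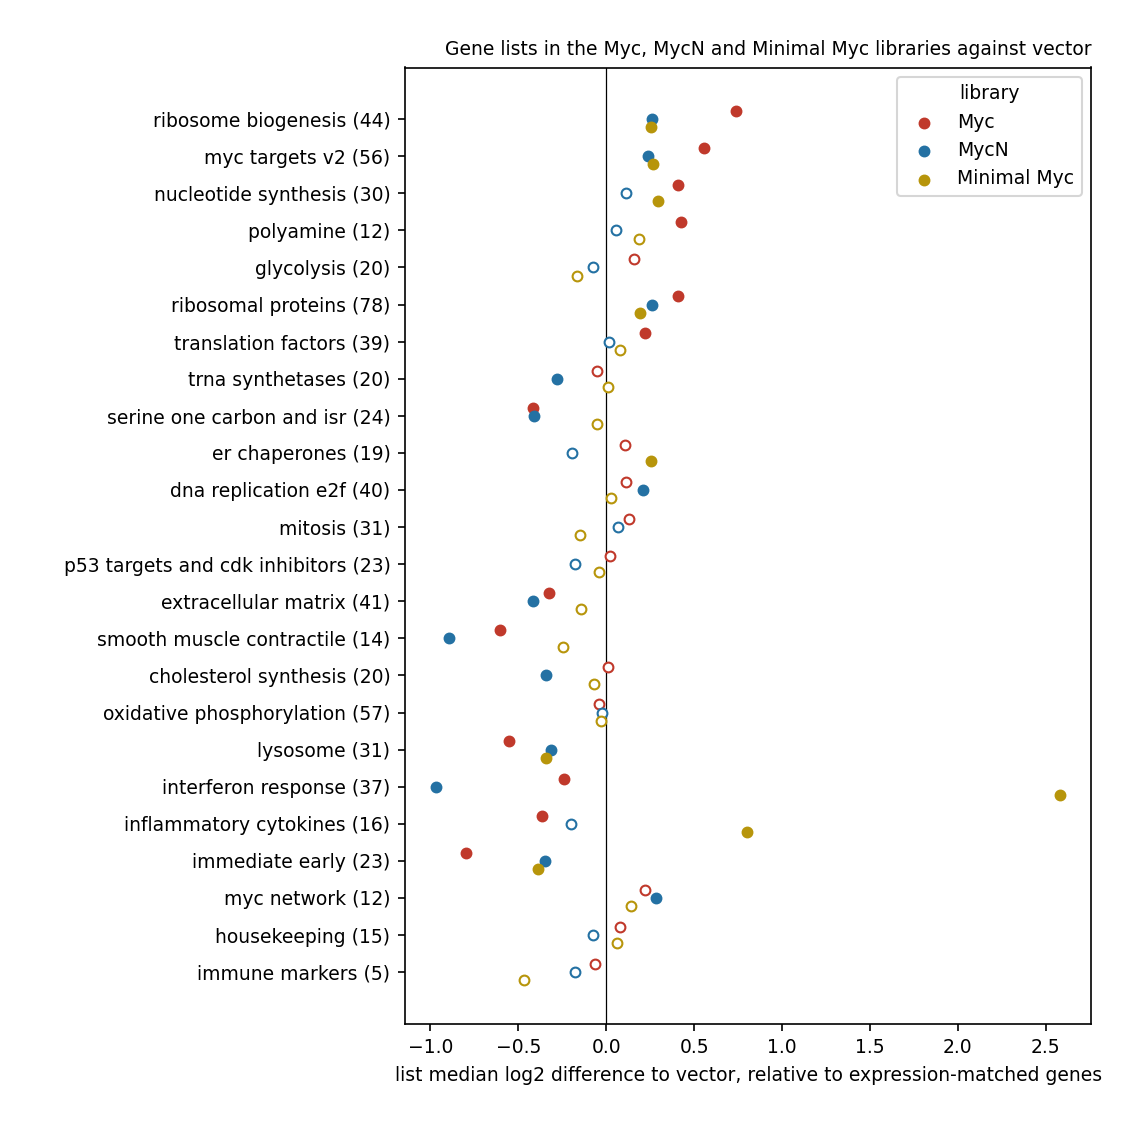
Median log2 difference to vector of each gene list relative to expression-matched genes (x axis), with measured members in brackets, for the Myc, MycN and Minimal Myc libraries. Filled points lie in the outer 2.5% of 10000 random lists at either end and open points between, with the interferon response at 2.58 in Minimal Myc and -0.97 in MycN.

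Against vector, the MycN library was higher in the same ribosome lists by a smaller margin. Ribosome biogenesis stood at 0.26 with 12 of 44 genes at least 2-fold higher, ribosomal proteins at 0.26 with 11 of 78, and Myc targets at 0.24 with 15 of 56. Relative to the median difference of all genes, 1 of 44, 0 of 78 and 3 of 56 were at least 2-fold higher. Srm was 190 FPKM against 56.9. DNA replication genes stood at 0.21 over 40, with Mcm3, a subunit of the replicative helicase, at 115 FPKM against 43.0. Contractile genes stood at -0.89 over 14, and 3 were at least 2-fold lower, among them Myl9, a myosin light chain, at 3.30 FPKM against 33.3 and Tagln, an actin-binding protein, at 29.4 against 147.

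Interferon response genes were also low in MycN, at -0.97 relative to matched genes (-0.54 before matching and -0.40 in scaled FPKM), with 13 of 37 at least 2-fold lower and 1 higher. Irf7, the transcription factor that amplifies type I interferon, was 0.685 FPKM against 7.41. Extracellular matrix (-0.41), serine and amino acid stress genes (-0.41), cholesterol synthesis (-0.34), lysosome (-0.31), tRNA synthetases (-0.28) and immediate early genes (-0.35) were below matched genes, though above 0 before matching. For tRNA synthetases the 95% bootstrap interval over members spanned 0 (-0.43 to 0.04). Nucleotide synthesis (0.11), polyamine synthesis (0.06), translation factors (0.01), mitosis (0.07), inflammatory cytokines (-0.20) and p53 targets (-0.18) lay within the range of random lists. The cytokine members went apart, with Lcn2, an iron-binding acute phase protein, at 55.2 FPKM against 4.04 and Ptgs2, an inducible prostaglandin synthase, at 16.9 against 70.6.

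The highest genes in MycN were Lars2 at 1145 FPKM, Mycn, Filip1l (52.1), Cdk8 (20.4) and Cep250 (15.7), of which all but Mycn are listed at 0 in vector, with Rtn4rl2 at 25.4 FPKM against 0.336, Slpi at 33.4 against 0.815 and Sema3f, an axon guidance ligand, at 22.9 against 0.716. Ranks of genes listed at 0 rest on a value that can be a failed estimate. The lowest were Acin1, Lce1g and Sprr2k, listed at 0 in MycN, with Tmsb4x, an actin-sequestering peptide (31.4 FPKM against 685), Sprr1a (0.182 against 23.6), Oasl1 (1.17 against 23.1), Sprr2h (0.0393 against 9.41) and Msln (3.73 against 38.6). In all, 890 genes were at least 2-fold higher and 216 lower. Centred counts were 216 and 488, and the scaled table gave 3193 and 145.

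Against vector, the Minimal Myc library had its largest list value in the interferon response. Of 37 genes, 34 were at least 2-fold higher and 0 lower, at 2.58 relative to matched genes, and 36 had their highest level in this library. Iigp1, an interferon-inducible GTPase, was 77.9 FPKM against 1.03, and Ifi44 was 136 against 4.35. Of 16 cytokine genes, 11 were at least 2-fold higher and 1 lower (0.80), with the acute phase gene Saa3 at 227 FPKM against 3.34 and the cytokine Il6 at 23.8 against 1.58.

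**Figure D3:**
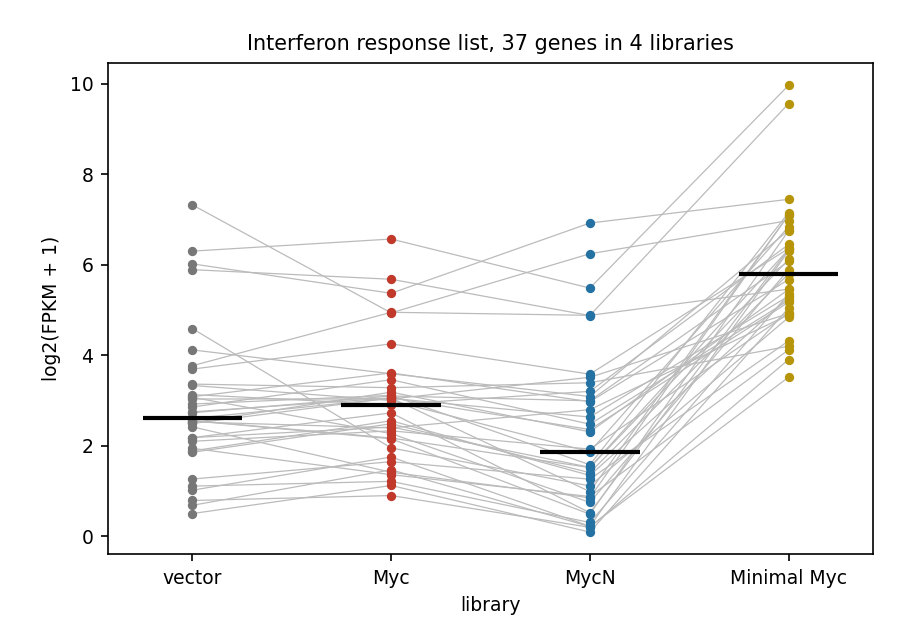
Level of the 37 interferon response genes in the 4 libraries as log2(FPKM + 1) (y axis). Points are genes, grey lines join the same gene and black bars are medians, with a median FPKM of 5.09 in vector, 6.52 in Myc, 2.66 in MycN and 54.7 in Minimal Myc.

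The ribosome lists were higher in Minimal Myc as well. Ribosome biogenesis stood at 0.26 with 18 of 44 genes at least 2-fold higher, ribosomal proteins at 0.19 with 24 of 78, Myc targets at 0.26 with 21 of 56 higher and 1 lower, and nucleotide synthesis at 0.30 with 13 of 30. Relative to the median difference of all genes, 3 of 44, 4 of 78, 4 of 56 and 1 of 30 were at least 2-fold higher, and 1 Myc target was lower. Npm1 was 1187 FPKM against 345 in vector. Endoplasmic reticulum chaperones stood at 0.26 over 19 genes, with Dnajc3, a co-chaperone, at 21.4 FPKM against 7.05. Lysosome (-0.34) and immediate early genes (-0.39) were below matched genes. For immediate early genes the 95% bootstrap interval over members spanned 0 (-0.81 to 0.22). The remaining lists lay within the range of random lists: polyamine synthesis (0.19), glycolysis (-0.16), translation factors (0.08), tRNA synthetases (0.01), serine and amino acid stress genes (-0.05), DNA replication (0.03), mitosis (-0.15), p53 targets (-0.04), extracellular matrix (-0.15), contractile genes (-0.24), cholesterol synthesis (-0.07), oxidative phosphorylation (-0.03) and housekeeping (0.06). Matching on length and GC content as well put mitosis at percentile 1.78 in place of 3.40.

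The highest genes in Minimal Myc were Rn45s at 1059 FPKM, Lars2 (343), Filip1l (57.4) and Cdk8 (33.0), all listed at 0 in vector, together with Mycn, Saa3, Iigp1 and Grb10, the last at 38.7 FPKM against 0.0977. Ranks of genes listed at 0 rest on a value that can be a failed estimate. The lowest were Gnl3l, listed at 0 in Minimal Myc, Atp6v0c-ps2 (0.0221 FPKM against 53.2), Spon2 (0.287 against 13.8), Pcdh10 (0.106 against 9.42), Psca (2.32 against 29.2), Hist2h2bb (1.36 against 17.5), Rmrp and Tinagl1 (8.68 against 56.9). In all, 1579 genes were at least 2-fold higher and 196 lower. Centred counts were 432 and 545, and the scaled table gave 3919 and 122.

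Between MycN and Myc, ribosome biogenesis stood at -0.36, Myc targets at -0.29, nucleotide synthesis at -0.37, glycolysis at -0.34 and ribosomal proteins at -0.16 relative to matched genes, each at a percentile of 0.03 or lower among random lists. Few members differed by 2-fold: 2 of 44, 2 of 56, 1 of 30, 1 of 20 and 2 of 78 were lower in MycN, and 1 Myc target was higher. Pa2g4 was 87.7 FPKM against 248 in Myc. Interferon response stood at -0.66 with 12 of 37 at least 2-fold lower and 2 higher, and immediate early genes at 0.32. For immediate early genes the 95% bootstrap interval over members spanned 0 (-0.21 to 0.44). Mycn, Cep250 (listed at 0 in Myc), the carbonyl reductase Cbr2 (33.0 FPKM against 1.11), the matrix protein Dpt (74.2 against 7.77) and the imprinted Notch-like gene Dlk1 (375 against 44.0) were highest. Rn45s and Acin1, listed at 0 in MycN, Tmsb4x (31.4 against 1462), Myc and Gas6 (0.0134 against 22.7) were lowest. In all, 227 genes were at least 2-fold higher and 319 lower, or 99 and 2351 in the scaled table.

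Between Minimal Myc and Myc, interferon response stood at 2.99 with 35 of 37 genes at least 2-fold higher, and 10 of 16 cytokine genes were at least 2-fold higher and 1 lower. Ribosome biogenesis stood at -0.35, Myc targets at -0.31, glycolysis at -0.31, mitosis at -0.26 and ribosomal proteins at -0.25, with 2 of 44, 3 of 56, 0 of 20, 0 of 31 and 0 of 78 members at least 2-fold lower and 1 ribosomal protein gene higher. Serine and amino acid stress genes stood at 0.29, with Cth, which makes cysteine from cystathionine, at 37.1 FPKM against 6.47. Mycn, Ifi44 (136 against 1.67), AF357425 (24.9, listed at 0 in Myc) and the nucleic acid sensor Zbp1 (107 against 3.46) were among the highest. Gnl3l (listed at 0 in Minimal Myc), Atp6v0c-ps2 (0.0221 against 15.7), Gas6 (0.574 against 22.7), Pla2g7 (1.02 against 14.4) and Col6a3 (2.45 against 22.5) were lowest. In all, 521 genes were at least 2-fold higher and 252 lower, or 284 and 2057 in the scaled table.

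Between Minimal Myc and MycN, interferon response stood at 3.63 with 33 of 37 genes at least 2-fold higher, and cytokines at 1.06 with 8 of 16 higher and 2 lower. Extracellular matrix stood at 0.48 with 15 of 41 higher and 5 lower, and endoplasmic reticulum chaperones at 0.43. For cytokines (-0.15 to 2.26) and extracellular matrix (-0.16 to 0.86) the 95% bootstrap interval over members spanned 0. Ribosome biogenesis (-0.04), ribosomal proteins (-0.09) and Myc targets (0.03) lay within the range of random lists. Timp1, a metalloproteinase inhibitor, was 708 FPKM against 60.8. Rn45s (listed at 0 in MycN), Zbp1 (107 against 0.407), Ifi44 (136 against 0.809), Usp18, which removes Isg15 from proteins (136 against 0.988) and Iigp1 (77.9 against 0.170) were highest. Atp6v0c-ps2 (0.0221 against 26.8), Cbr2 (0.811 against 33.0), the MHC class II invariant chain gene Cd74 (2.06 against 42.9), Rtn4rl2 (log2 difference -3.58) and the sulfatase Sulf2 (1.42 against 26.4) were lowest. In all, 808 genes were at least 2-fold higher and 429 lower.

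Across 11640 genes, which are not independent replicates, differences from vector had Pearson's r of 0.584 between Myc and MycN, 0.522 between Myc and Minimal Myc and 0.259 between MycN and Minimal Myc (Spearman's rho 0.568, 0.527 and 0.254). Simulated libraries without any difference gave 0.50 for each pair, which follows from sharing vector and giving every library the same noise. The simulation holds no shift of all genes, so the uncentred counts of shared genes below are not like for like with it. The covariance lay 0.0583 and 0.0646 above the simulated one for the first pairs and -0.0334 from it for the last; the simulated noise includes real differences between Myc and MycN. Of genes at least 2-fold higher, 373 were shared by Myc and MycN, 553 by Myc and Minimal Myc and 253 by MycN and Minimal Myc. Independent lists would share 99.4, 176 and 121, and simulated unchanged libraries 61.7, 61.9 and 61.8. With libraries centred on the median difference, an alternative added after seeing the data, 55, 59 and 39 were shared (independent 4.05, 8.09 and 8.02), each below the simulated number. Of genes at least 2-fold lower, 75, 84 and 49 were shared, against 3.38, 3.06 and 3.64 for independent lists and 63.0, 62.1 and 61.8 simulated, and centred libraries shared 218, 251 and 148 (independent 21.4, 23.9 and 22.8). The shared numbers thus depend on the centring in both directions. Part of any excess may come from the shared vector library, which cannot be split.

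Markers of other cell types mostly lay below the filter of 1 FPKM on average. Krt19, the only epithelial marker past it of 15, was 13.2 FPKM in vector, 10.6 in Myc, 4.34 in MycN and 1.66 in Minimal Myc. Of 14 immune markers 5 passed it, with list values of -0.06, -0.18 and -0.47 against vector in Myc, MycN and Minimal Myc. Cd74 was 42.9 FPKM in MycN and 2.06 to 6.96 elsewhere. Flt1, the only endothelial marker past it of 12, was 0.393, 0.669, 3.42 and 0.291 FPKM. Of 12 adipocyte markers 4 passed it, and Fabp4, a fatty acid carrier, was higher in MycN than in vector by 2.65 (log2). The 2 skeletal muscle markers past it were Acta1 (13.8, 18.2, 16.1 and 19.7 FPKM) and Tnnt2 (6.91, 6.97, 10.6 and 9.46), and the 3 neural ones were led by Tubb3 (20.6, 12.6, 16.3 and 8.88).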

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

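The tests of immune cells and of the culture were chosen only after the interferon result was seen, and the immune cell test after other forms of it had been run.

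The interferon response lay in opposite directions from matched genes in comparisons with the same vector library, at -0.24 in Myc, -0.97 in MycN and 2.58 in Minimal Myc. Before matching its medians were 0.23, -0.54 and 3.05 (log2), so in Myc the direction holds only relative to other genes. Inflammatory cytokines did likewise relative to matched genes, at -0.37 in Myc and 0.80 in Minimal Myc. Before matching their medians were 0.23 and 1.42, and in Myc 2 of 16 genes were at least 2-fold higher and 0 lower. Their direction in Myc thus also holds only relative to other genes. The difference between these comparisons was not tested, because each group has 1 library.

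For the interferon genes in Minimal Myc, immune cells that carried these transcripts are argued against: over 14 immune markers the largest gain from vector was 5.97 FPKM, in Cd14, against a median gain of 42.5 FPKM over the interferon list. Cd53 was also higher (5.08 FPKM against 0.473), while abundant leukocyte genes such as Laptm5 (0.0205 FPKM) and Lyz2 (0.0395) were no higher than in vector. A further 4 markers are listed at 0 in Minimal Myc, which is not read either way because an estimate can fail. Signals from a small number of immune cells are not excluded by these levels. The culture, or the adenovirus exposure of that 1 library, cannot be told apart from the Minimal Myc protein, because the group has 1 library. An effect of Minimal Myc itself stays open and untested for the same reason.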

How the results depend on the processing

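Of 144 list values, all stayed within the 95% bootstrap interval over their own members (2000 draws, a spread of genes and not of replicates) with a pseudocount of 0.1, a minimum of 5 FPKM, scaled FPKM and centred libraries, and 143 without a filter; the exception was ribosomal proteins in Myc against vector (0.45 in place of 0.41). Centring and scaling move a list and its matched genes nearly alike, so they test these values little. Matching on length and GC content, added after seeing the data, moved 6 of 144 lists across the edge of the random range and turned 0 to the other edge. 3 alternatives for the gene counts were also added after seeing the data (genes listed at 0 left out, coding genes alone, interferon list left out), and all 12 counts stayed within 1.5 times under each. No paired analysis was possible because the labels give no replicate numbers and each group has 1 library. Depth is unknown, so no value has a counting error. The causes below were not tested unless the setting itself changes the count.

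Counts are given as higher and lower at 2-fold in the order Myc, MycN and Minimal Myc against vector, then MycN against Myc, Minimal Myc against Myc and Minimal Myc against MycN. At 1.5-fold they were 4587 and 452, 3866 and 481, 4679 and 473, 750 and 1115, 1215 and 870, and 1968 and 1306. At 3-fold they were 158 and 66, 139 and 78, 353 and 55, 67 and 101, 257 and 84, and 347 and 119. Centred libraries gave 218 and 510, 216 and 488, and 432 and 545 against vector, with the rest within 1.5 times. The scaled table gave 9139 and 58 for Myc, 3193 higher for MycN, 3919 and 122 for Minimal Myc, 99 and 2351 for MycN against Myc, and 284 and 2057 for Minimal Myc against Myc. With a pseudocount of 0.1 there were 303 lower in Myc, 1426 higher in MycN, 359 lower in Minimal Myc, 376 higher in MycN against Myc, 420 lower in Minimal Myc against Myc and 685 lower in Minimal Myc against MycN. A minimum of 5 FPKM, which tests fewer genes, left 85, 134 and 83 lower against vector, 119 higher in MycN against Myc, 333 and 126 in Minimal Myc against Myc, and 203 lower in Minimal Myc against MycN. Keeping small RNA genes gave 274 lower in Myc and 301 lower in Minimal Myc.

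Without a filter the median difference to vector was 0.12 in Myc, 0.12 in MycN and 0.098 in Minimal Myc, and with scaled FPKM it was 0.89, 0.37 and 0.34; many genes then sit near 0 in every library. The ratio of summed FPKM gave 0.68 for Myc and 0.69 for Minimal Myc (scaled 1.71 and 1.05), and housekeeping genes 0.77 and 0.73 (scaled 1.79 and 1.09). A pseudocount of 0.1 gave 1.56 for Myc in the scaled table. Without a filter Pearson's r was 0.653 for Myc and MycN, 0.615 for Myc and Minimal Myc and 0.387 for MycN and Minimal Myc.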

Other observations

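The gene groups of the first paragraphs were chosen after their values were seen; the tests of the higher level of all genes were set before their values were computed, but after summed FPKM per library had been seen.

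By FPKM some MHC class I genes were highest in Minimal Myc. H2-K1, a classical class I heavy chain, was 174 FPKM in vector, 136 in Myc, 159 in MycN and 414 in Minimal Myc, and H2-D1 was 143, 101, 149 and 327. Class I genes are near-identical to each other, so their single values are uncertain. B2m, their shared light chain, was 1269, 911, 1073 and 2324 FPKM in the same order, but its NanoString signal was 46911, 62438, 22834 and 57149, highest in Myc. Isg15, a ubiquitin-like interferon product, was 58.4 FPKM in vector and 753 in Minimal Myc.

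Some genes were near absent in 1 library and abundant in another. A total of 42 genes were above 0 but under 0.5 FPKM in a library and at 10 FPKM or more in another. Of them 31 were under 0.5 in MycN and 35 reached 10 in Minimal Myc, and 7 belong to the fixed interferon list of 37 genes. That list does not hold every interferon-induced gene, so the others are not shown to be unrelated to interferon. Sfrp1, a secreted Wnt inhibitor, was 0.198 FPKM in vector, 5.58 in Myc, 0.138 in MycN and 33.9 in Minimal Myc. Meg3, an imprinted non-coding RNA, was 0.124, 0.0365, 1.21 and 12.8. The 3 Sprr genes measured were all highest in vector. No explanation was tested for these genes.

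For the median gene being above vector in all 3 comparisons of unscaled FPKM, a few abundant messenger RNAs that took the fragments of vector are argued against, because leaving out the 50 most abundant coding genes moved the log2 ratio of coding sums by at most 0.0114. Fragments outside messenger RNA may account for part or all of the shift. The sum of FPKM times transcript length over coding genes was higher than in vector by 0.611, 0.444 and 0.636 (log2) in Myc, MycN and Minimal Myc. The median differences were 0.473, 0.419 and 0.473. FPKM are scaled to the library total, so a higher median gene raises this sum nearly by construction. The sum is thus no separate support. RNA without a poly(A) tail is a candidate source: all 54 histone genes lay below the all-gene median in each comparison, with medians at least as far as -0.934 from it, while the DNA replication list, which also follows DNA synthesis, was not low (0.11, 0.21 and 0.03). Rmrp (118, 22.5, 57.7 and 14.9 FPKM in vector, Myc, MycN and Minimal Myc) and Rpph1 (55.9, 12.2, 35.6 and 11.6), also without a tail, were highest in vector, and Rn45s, listed at 0 in vector and MycN, is not read either way. More messenger RNA per cell under the Myc proteins, which unscaled FPKM cannot show, stays open.

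In the scaled table the ratio to vector of the 30 NanoString genes was a median of at least 1.76 times the NanoString ratio of the same gene in each of the 3 libraries. This follows from the construction, since the factor is the mean NanoString ratio and multiplied FPKM that already differed between libraries. The NanoString normalization is not given in the sources used here, so which of the tables is nearer to RNA per cell stays open. No biological explanation was tested.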
